A study of Mus musculus with 56 samples.

How the data were processed

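The labels describe CUT&Tag on mouse embryonic stem cells with doxycycline-inducible Rnaseh1, with or without doxycycline. All 56 libraries were placed in groups by target and treatment from their labels. The deposited files analysed here concern H2A.Z, with 4 control and 4 doxycycline libraries. The design text also names a ZX-1 line, which no sample label gives, so no line is used here to set apart an effect of doxycycline itself.

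Per the submitters' processing notes, Trimmomatic, Bowtie2, Picard, HOMER and deepTools were used with the genome build GRCm38. The roles and versions of these tools, the peak caller, the test behind the lists of changed peaks, its threshold and whether replicates were pooled are not given in the sources used here. Per the file headers, the lists of lower and higher peaks were annotated with HOMER annotatePeaks. The peak score the authors deposited is 0 for every peak and was not used. Positions and distances to the TSS were used as the authors deposited them, and starts are printed counting from 1.

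The 61420 peaks do not overlap one another, have a minimum width of 501 base pairs, and lie at least 2001 base pairs apart. All 9077 lower and 318 higher peaks had the exact coordinates of a peak of the set, and the remaining 52025 were taken as unchanged, meaning that neither list holds them. Gene symbols in the lists were read through their Entrez IDs from a table of RefSeq genes of GRCm38.p6, which matched 9042 lower and 315 higher peaks. That table has gene starts and ends and no strand or sequence. A gene end is therefore the start or the end of a protein-coding or lncRNA gene, and a peak was counted there if its centre lay within 1 kb. For gene lists, genes of every type in the table were used, with the same window. This departs from the design fixed before the data were examined, which used the TSS. GC content, GC skew and sizes of change, which that design also held, were not analysed here.

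Annotation classes, positions, gene lists and chromosomes were compared with two-sided Fisher's exact tests with Benjamini-Hochberg adjustment within each family and odds ratios with 95% Woolf intervals. Shares have 95% Clopper-Pearson intervals, which cover counting only, and a count of 0 was given the limit of 3 counts. Medians were compared by two-sided permutation tests with 100000 resamples. Gene lists matched on summed peak width were tested otherwise, by redrawing calls 100000 times within 5 classes of that width, with Mantel-Haenszel odds ratios. Ranges over alternatives for lower peaks include the adjusted p-values of these redraws. The background for gene lists was the 16463 genes with a peak at an end, and lists with fewer than 5 such genes were not tested. The 37 lists were fixed before the data were examined. Genes were named by a rule fixed then: the 15 lower and up to 10 higher promoter peaks first in fold change, or in width where no fold, p-value or score ranks them, leaving out unnamed gene models, the 4 first members of each list past the threshold and up to 3 of others, 14 lineage, pluripotency, H2A.Z and Rnaseh1 genes, and the 5 genes with most lower and most higher peaks. Further genes, such as the 4 with a higher peak near a TSS and members of H2A.Z exchange complexes, were chosen after their values were seen. Repeat classes were likewise chosen after the lists were seen. Of the genes that these rules name, 1 is not reported here.

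The list test was tested on simulated data with the real peaks and genes. Of 50 simulations with an odds ratio of 5 for the peaks of a list, 78% called the mesoderm list (24 genes with a peak), and 0.286% of unchanged lists were called. Calls were drawn independently for each peak, at the same rate for all peaks outside the changed lists. The simulations therefore do not cover neighbouring peaks that are lower together, and odds ratios under 5 were not tried. The permutation test of widths gave p under 0.05 in 6.4% of 500 draws without a shift. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, SciPy 1.17.1, matplotlib 3.10.9 and bedtools 2.31.1 were used. Alternatives covered the window (500 base pairs and 3 kb), the overlap rule, width-matched unchanged peaks, chromosomes, backgrounds and peaks of minimum width.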

Results

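CUT&Tag, in which an antibody tethers a transposase to chromatin so that tagged fragments mark where a protein or histone mark lies, was carried out in mouse embryonic stem cells that carry a doxycycline-inducible, HA-tagged Rnaseh1. RNase H1 degrades the RNA strand of RNA:DNA hybrids, so its induction serves to remove R-loops, and the comparison of treated with untreated cells asks where H2A.Z, a variant of histone H2A found at promoters and enhancers, then changes. The induction itself was not measured here. The labels list 56 libraries for 10 targets, IgG included. H2A.Z had 4 control libraries and 4 libraries from cells given 500 ng/ml doxycycline for 48 hours. All cells were grown in 2i/LIF medium with 2% FBS, 1 µM of the MEK inhibitor PD0325901 and 3 µM of the GSK3 inhibitor CHIR99021, which activates Wnt signalling. The other 48 libraries, among them H3K4me3, H3K27me3, H3K27ac, H3K36me3, H3K9me3, H3.3, H4ac and elongating RNA polymerase, are not analysed here. The deposited H2A.Z data were 61420 peaks on GRCm38 and the authors' lists of peaks with lower and with higher H2A.Z. Lower and higher are read as doxycycline relative to control from the names of the lists, since the file headers do not state the contrast. The lists give positions and gene annotation with no fold change, p-value or value per library, so sequencing depth and the spread between replicates are unknown here, and the p-values below compare peaks or genes, which are not independent replicates.

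H2A.Z was lower at 9077 peaks and higher at 318. Lower peaks made up 96.6% of the 9395 changed peaks (95% exact Clopper-Pearson interval 96.2 to 97.0%). They were 14.8% of the whole peak set (14.5 to 15.1%), and higher peaks were 0.518% (0.463 to 0.578%). In the widest 50% of the set these shares were 15.9% (15.5 to 16.3%) and 0.0749% (0.0475 to 0.112%). These intervals cover the counting of peaks only. Lower peaks were assigned to 6690 genes, of which 474 had 3 or more. Gse1, which encodes a coiled-coil nuclear protein, had 12 lower peaks between positions 120368803 and 120514519 of chromosome 8, and the adjoining A330074K22Rik had 9 between 120228815 and 120348648. Of these, 9 at each gene were intergenic, and the median distances from the TSS were 44.4 and 67.0 kb. Casz1, a zinc finger transcription factor of heart and vessel development, Nol4l and the urate transporter gene Slc22a12 had 8 each, at medians of 18.9, 28.4 and 60.3 kb. The authors' annotation assigns no unchanged peaks, so no share per gene is given. The 318 higher peaks were assigned to 275 genes. Adcyap1, Hgf, Il5ra and Slitrk5 had 3 each, at median distances from the TSS of 591, 414, 134 and 138 kb, and a further 32 genes had 2.

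Lower peaks lay at gene ends and inside genes more often than unchanged peaks, and higher peaks less often. Of the lower peaks, 38.0% were centred within 1 kb of an end of a protein-coding or lncRNA gene, against 18.6% of the unchanged peaks and 4.40% of the higher peaks. The odds ratio of lower against unchanged was 2.69 (2.57 to 2.83; two-sided Fisher's exact test, −log10 p of 339), and that of higher against unchanged was 0.202 (0.118 to 0.345; adjusted p = 1.67e-13). Of the lower peaks, 70.5% lay inside a gene, against 49.1% of unchanged and 34.3% of higher peaks. Against width-matched unchanged peaks the odds ratio of lower peaks at gene ends was 2.48 (2.32 to 2.65). Peak height is unknown here, so these contrasts may also follow how easily a peak could be called. In the authors' annotation, 1713 lower peaks (18.9%) were in promoters, 1444 (15.9%) in exons and 410 (4.52%) in 5′ UTRs, while 233 of the 318 higher peaks (73.3%) were intergenic and 1 was in a promoter. The promoter share differed between the lists (odds ratio 73.8, 10.4 to 526, Fisher's exact test, adjusted p = 2.43e-26), a ratio that rests on 1 higher peak and was 35.1 (16.6 to 74.3) within 3 kb of a TSS, and that of introns was not distinguishable (27.8% and 23.6%, adjusted p = 0.148). Median distance to the nearest TSS was 5.57 kb for lower and 110 kb for higher peaks (two-sided permutation test, p = 1e-05, the smallest that 100000 resamples can give). Because strand was not used here, gene ends stand in for TSSs in the comparison with unchanged peaks, and 84.1% of lower peaks at gene ends were within 1 kb of a TSS in the authors' annotation.

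**Figure D1:**
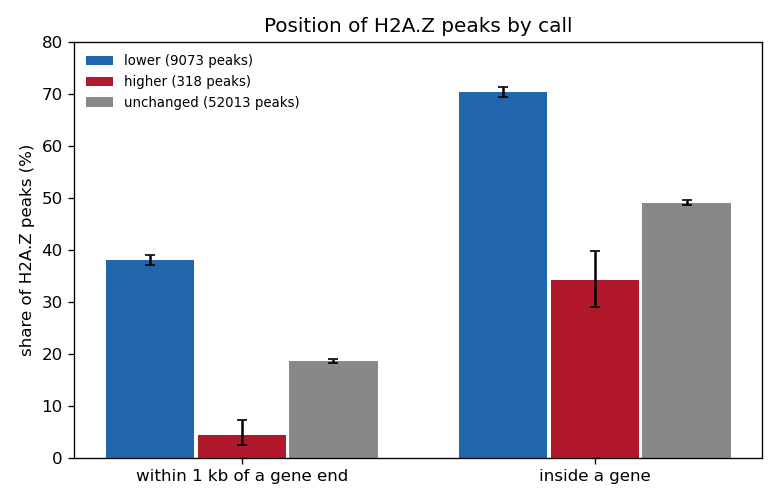
Share of H2A.Z peaks (percent) within 1 kb of a gene end and inside a gene, for lower, higher and unchanged peaks, with exact 95% intervals. Lower peaks stand at 38.0% and 70.5%, unchanged peaks at 18.6% and 49.1%, and higher peaks at 4.40% and 34.3%.

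Lower peaks were slightly wider than unchanged peaks, with medians of 1034 and 967 base pairs (permutation test, p = 1e-05, the smallest possible). Higher peaks were narrow, with a median of 501 base pairs, the minimum width in the set, which 52.5% of them had (permutation p = 1e-05 against unchanged peaks). Lower peaks were most frequent in the eighth decile of width, at 19.4%, and least frequent in the widest decile, at 9.90%. That widest decile held 0 higher peaks.

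With no fold change to rank by, promoter peaks were ranked by width. The widest lower promoter peak was one of 9726 base pairs at Irx3, a homeobox gene of neural patterning (chromosome 8, 91797315 to 91807040, centred at −523 base pairs from the TSS). It was followed by Smarcd3, a BAF remodelling subunit of heart and muscle (9548 base pairs), Msx1, a homeobox gene of neural crest and limb (8619), Smpd5 (7175), the myosin-binding protein gene Mybpc2 (6895), Nkx3-2 (6814), Fgf11 (6807) and Slc22a12 (6437). The atrial myosin light chain gene Myl7 (6141), Emp3 (5838), Dpf1 (5746), the endoderm factor Foxa2 (5645), Foxl2os (5570), Zfp423 (5558) and Lncpint (5448) completed the 15. The only higher promoter peak was at the olfactory receptor gene Olfr874 (chromosome 9, 37745239 to 37745882, 644 base pairs).

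Neuroectoderm genes carried lower H2A.Z more often than other genes. Of 26 with an H2A.Z peak at a gene end, 16 (61.5%, 40.6 to 79.8%) had a lower peak, against 4444 of the 16437 other genes with a peak (odds ratio 4.32, 1.96 to 9.52, Fisher's exact test, adjusted p = 0.00416 over 35 lists). The widest were at Irx3, Msx1 and Irx5 (5317 base pairs). Not all of the 16 were at a TSS of the gene. The lower Nkx6-1 peak lay 5214 base pairs from the TSS, and the peak at the other end of that gene was unchanged. At Dlx1 the lower peak was annotated at the transcript's end and assigned to Dlx1as, 3114 base pairs from its TSS. Among mesoderm genes 14 of 24 had a lower peak (58.3%, odds ratio 3.78, exact adjusted p = 0.0204), the widest at Tbx1, Fgf3, Foxf1 and T, the primitive streak factor Brachyury. Among FGF and MAPK feedback genes 13 of 23 had one (odds ratio 3.51, exact adjusted p = 0.03), led by Fgfr4 and the phosphatase genes Dusp4 and Dusp9, and then Fgf3. The lower Fgfr4 peak lay 16561 base pairs from the TSS, and the peak at the other end of that gene was unchanged. Of the Hox genes 12 of 22 had a lower peak (odds ratio 3.24, exact adjusted p = 0.0476), the widest at Hoxb13, Hoxc11, Hoxc10 and Hoxc9. Formative and primed pluripotency genes (Sox3, Pou3f1, Grhl2 and Fgf5 the widest) and fibroblast markers (Twist2, Fbn1, Loxl1 and Col5a1 the widest) each had 8 of 13 (odds ratio 4.31, exact adjusted p = 0.0476). The fibroblast list was fixed as markers of feeder cells, and its odds ratio is as high as that of neuroectoderm genes, but the mix of cell types in each library was not measured here. The formative and FGF lists share 3 genes, Fgf5, Fgf8 and Etv4. At tRNA genes lower peaks were rarer, at 7 of 109 (6.42%, odds ratio 0.183, exact adjusted p = 1.97e-06).

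Most of these calls depended on the setting. Protein-coding genes with a peak had a lower one in 31.5% of cases, lncRNA genes in 19.3%, pseudogenes in 14.2% and miRNA genes in 39.3%. The tRNA call was made against genes of all types and was not matched on gene type. Against protein-coding genes only, a comparison added after the data were seen, neuroectoderm kept its call in the exact test (odds ratio 3.50, adjusted p = 0.0314, range over 7 alternatives 1.53e-06 to 0.0317), while mesoderm (odds ratio 3.06, adjusted p = 0.0594, range 1.07e-04 to 0.0646), FGF and MAPK feedback (odds ratio 2.84, adjusted p = 0.086, range 1.72e-05 to 0.086), Hox (2.62, 0.116, range 4.61e-04 to 0.134), formative pluripotency (3.49, 0.116, range 4.99e-04 to 0.301) and fibroblast markers (3.49, 0.116, range 0.00116 to 0.167) did not, and tRNA genes left the comparison. Hox, formative pluripotency and fibroblast lists also lost their calls against all gene types with matching on summed peak width or without peaks of the minimum width. With matching the Mantel-Haenszel odds ratios stayed close, at 3.17, 4.39 and 4.23, and the calls were lost narrowly. With nearest genes and within 3 kb, formative pluripotency (odds ratios 2.04 and 3.00) and fibroblast markers (2.30 and 2.37) lost their calls too, while Hox kept its call. In the exact test against protein-coding genes, mitochondrial ribosomal protein genes (7 of 53, odds ratio 0.33, adjusted p = 0.0314, range over 7 alternatives 0.0314 to 1) and Zfp genes (57 of 269, odds ratio 0.579, adjusted p = 0.00612, range 4.61e-04 to 0.416) had a lower peak less often than other genes, but neither held across settings. Against all genes, with a peak or without, Zfp genes had one more often (odds ratio 1.79, exact adjusted p = 4.61e-04) and mitochondrial ribosomal protein genes did not differ detectably (odds ratio 1.01, exact adjusted p = 1), and with nearest genes neither was called (odds ratios 0.876 and 0.893).

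**Figure D2:**
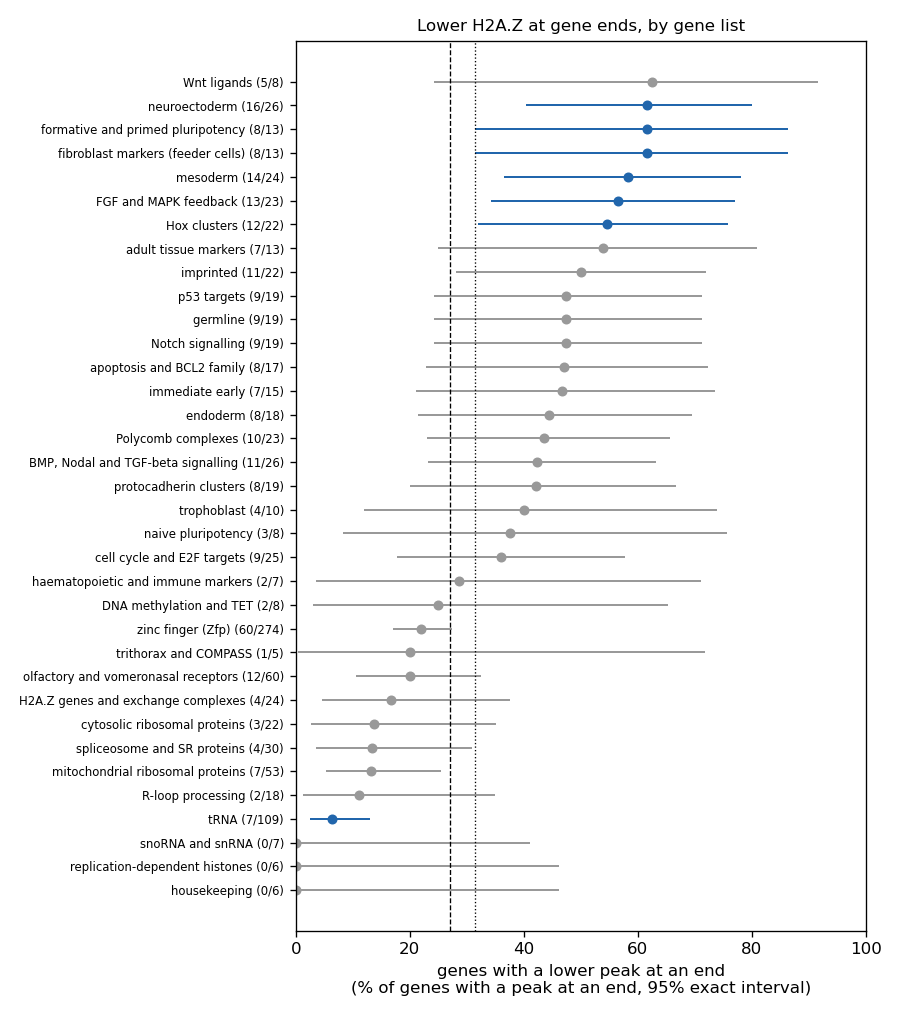
Percent of genes with a lower H2A.Z peak among genes of each list that have a peak at an end, with exact 95% intervals and counts in brackets. Blue marks adjusted p under 0.05, the dashed line is the share of all genes with a peak (27.1%) and the dotted line that of protein-coding genes (31.5%). Neuroectoderm stands at 61.5% and tRNA genes at 6.42%.

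The other 28 lists tested did not pass the threshold in this test. Above the overall share stood Wnt ligands (5 of 8, Wnt11 the widest), adult tissue markers (7 of 13), imprinted genes (11 of 22, among them Dlk1, Peg10 and Rasgrf1), p53 targets, germline genes and Notch signalling genes (9 of 19 each), apoptosis genes (8 of 17), immediate early genes (7 of 15), endoderm genes (8 of 18, with Foxa2, Gsc and Onecut1), Polycomb genes (10 of 23), BMP, Nodal and TGF-beta genes (11 of 26), protocadherins (8 of 19), trophoblast genes (4 of 10), naive pluripotency genes (3 of 8, Gbx2, Nr0b1 and Socs3), cell cycle genes (9 of 25) and haematopoietic markers (2 of 7). Below it stood DNA methylation and TET genes (2 of 8), Zfp genes (60 of 274), olfactory and vomeronasal receptors (12 of 60), COMPASS genes (1 of 5), H2A.Z exchange complexes (4 of 24, Znhit1, Dmap1, Epc2 and Mcrs1), cytosolic ribosomal proteins (3 of 22), splicing factors (4 of 30), mitochondrial ribosomal proteins (7 of 53) and R-loop processing genes (2 of 18, Fancm and Ddx23). Housekeeping genes and replication-dependent histones had 0 of 6 each, and snoRNA and snRNA genes 0 of 7. General pluripotency (3 genes with a peak) and two-cell-like genes (2) had too few for a test. Some of the 28 passed in other settings. With nearest genes, Wnt ligands (15 of 18, odds ratio 11.5, exact adjusted p = 8.82e-05), Notch signalling genes (17 of 24, 5.59, 4.46e-04), protocadherins (30 of 51, 3.29, 2.96e-04), immediate early, germline, imprinted and endoderm genes had a lower peak more often than other genes, and olfactory and vomeronasal receptors (63 of 373, 0.462, 9.22e-08) and cytosolic ribosomal proteins less often. In that setting a gene with more peaks has more chances of a lower one, and the number of peaks per gene was not matched. Within 3 kb, Wnt ligands (12 of 18, 5.34, 0.00444), Notch signalling genes (16 of 23, 6.10, 3.50e-04), protocadherins (30 of 53, 3.49, 1.36e-04), germline, imprinted and Polycomb genes had one more often, and olfactory and vomeronasal receptors (16 of 115, 0.429, 0.00444) and splicing factors less often. Against all genes, with a peak or without, 16 of the 28 passed.

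Of the lineage genes fixed beforehand, T (chromosome 17, 8432842 to 8435392), Mixl1 (chromosome 1, 180696172 to 180698018), Foxa2 (chromosome 2, 148043676 to 148049320) and the neural factor gene Sox1 (chromosome 8, 12395112 to 12397803) had a lower peak at a gene end. The endoderm gene Sox17 had a lower intronic peak (chromosome 1, 4491545 to 4493953) and an unchanged peak at a gene end. Pax6, Eomes, Rnaseh1 and the H2A.Z gene H2afz had a gene-end peak in neither list. Gata6, the pluripotency genes Pou5f1, Sox2 and Nanog, and H2afv had no peak of the set at a gene end. H2A.Z at Rnaseh1 says nothing of its induction.

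Higher peaks were rare at gene ends, and 17 of the 16463 genes with a peak had one at an end. Olfactory and vomeronasal receptor genes made up 4 of these 17 (4 of 60 with a peak, odds ratio 90.1, 28.5 to 285, Fisher's exact test, adjusted p = 1.28e-05). All 4 higher peaks within 1 kb of a TSS were at such genes, Olfr820, Olfr1126, Olfr1043 and Olfr874, which encode odorant receptors. With each peak given to its nearest gene whatever the distance, 11 of 373 such genes had a higher peak (odds ratio 2.51) and the call was lost (exact adjusted p = 0.227, range over 5 alternatives 4.15e-07 to 0.227).

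In introns and intergenic DNA, where the authors' annotation names repeats, the lists fell in different elements. L1Md elements, the young L1 retrotransposons of the mouse, held 965 of 5193 lower peaks (18.6%, 17.5 to 19.7%) and 1 of 308 higher peaks (odds ratio 70.1, 9.83 to 500, Fisher's exact test, adjusted p = 9.09e-25). L1Md_T with 475 and L1Md_A with 394 led them. Elements of the ERVK family, long terminal repeats and internal sequences counted together, held 89 higher peaks (28.9%, 23.9 to 34.3%) and 122 lower peaks (2.35%). The odds ratio of higher against lower was 16.9 (12.5 to 22.9, exact adjusted p = 2.50e-58). Among peaks of the minimum width, a comparison added later, it was 7.10 (4.48 to 11.2), so part of the ratio goes with width. Of the ERVK peaks that were higher, 56 were in RLTR13 elements, which held 0 lower peaks (exact adjusted p = 5.02e-72), led by RLTR13D6 (16), RLTR13B1 (14), RLTR13G (11) and RLTR13E (7). Older L1 elements named by Lx and at most a number held 15 higher peaks (4.87%) and 10 lower peaks (0.193%, exact adjusted p = 4.70e-13). Lettered Lx subfamilies such as Lx8b, with 2 lower peaks, were not counted there. CpG islands held 719 lower peaks (13.8%) and 0 of 308 higher peaks, which allows a share of up to 0.974%. SINEs did not differ detectably (3.20% and 3.57%, exact adjusted p = 0.738). These 10 classes were chosen after the lists were seen, and unchanged peaks carry no repeat annotation, so the comparison is between the lists only. Mappability was not analysed, so reads shared between copies of a repeat, L1Md included, may bear on these counts.

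**Figure D3:**
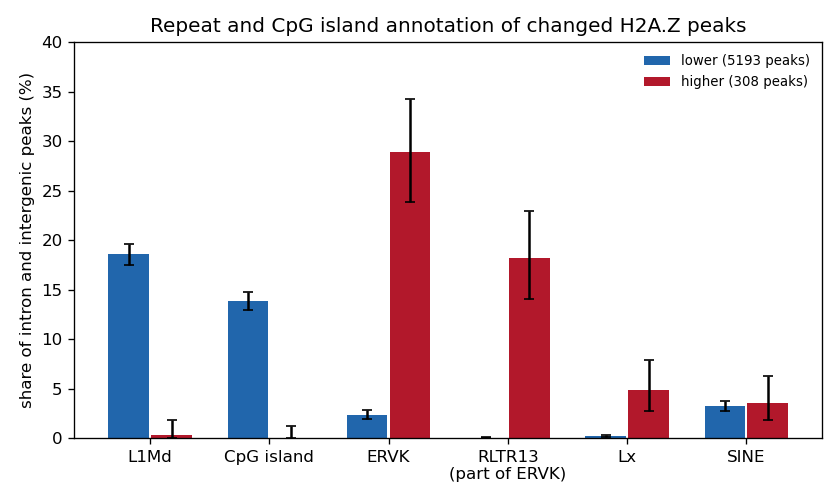
Share of intron and intergenic changed peaks (percent) in each repeat class or CpG island, for 5193 lower and 308 higher peaks, with exact 95% intervals. L1Md holds 18.6% of lower peaks and ERVK holds 28.9% of higher peaks.

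Chromosomes differed in their share of lower peaks. It ran from 9.36% on chromosome 3 to 21.2% on chromosome 11, and X had 20.4% (18.4 to 22.6%). Of 20 chromosomes, 9 lay above and 9 below the rest (Fisher's exact test, adjusted p under the threshold). Across the 20 chromosomes the share of lower peaks followed the share of peaks at gene ends (Pearson r = 0.916, Spearman rho = 0.878, permutation p and adjusted p = 2e-05 for both, the smallest that this two-sided test, which doubles a one-sided p, can give; r = 0.934 without chromosomes 3 and 7). Among peaks at gene ends 9 of the 20 still differed from the rest, each in the same direction as over all peaks, among them chromosome 11 (34.7% lower, odds ratio 1.54, exact adjusted p = 1.79e-08) and chromosome 3 (16.1%, odds ratio 0.523, exact adjusted p = 5.57e-09), so the share at gene ends does not account for all of the differences. There X did not stand above the other chromosomes (23.8%, odds ratio 0.87, exact adjusted p = 0.348). Copy number was not measured here, so a change of copies stays open, as untested, for chromosomes 11 and 3.

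**Figure D4:**
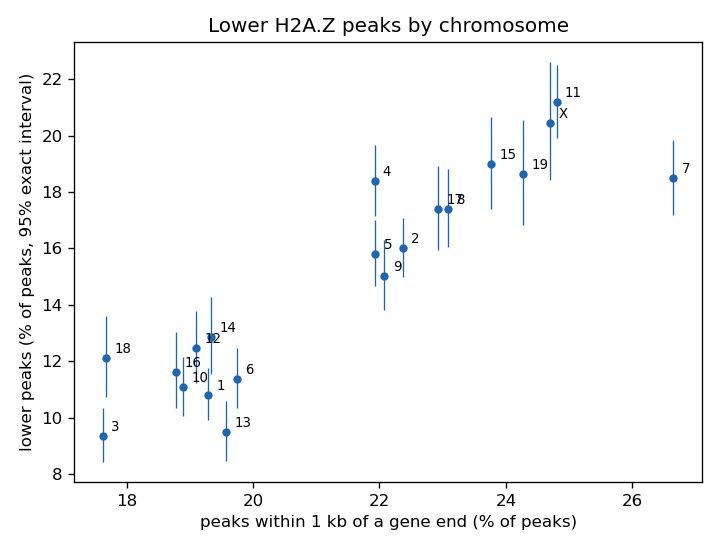
Percent of H2A.Z peaks that were lower, with exact 95% intervals, against the percent of peaks within 1 kb of a gene end, 1 point per chromosome (1 to 19 and X). Chromosome 3 is lowest at 9.36% and chromosome 11 highest at 21.2%.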

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

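Settings that use protein-coding genes, peaks of the minimum width or peaks over 50 kb from a TSS, widths without X, Y and unplaced contigs, and TSS distances of lower peaks drawn to the widths of higher peaks were chosen after the data were seen. No paired analysis was possible because the files hold no value per library. For the same reason a stricter threshold, leaving out each replicate and the sizes of change were not run, and GC content was not run without sequence. Merging peaks within 1 kb moved nothing, since no peaks lie that close. The gene-end, promoter, distance, width and ERVK comparisons kept their direction and side of the threshold under the alternatives run. For L1Md over 50 kb from a TSS, 687 of 1459 lower and 0 of 209 higher peaks give no odds ratio. Without peaks of the minimum width, lower peaks were 98.1% of changed peaks, and in the widest 50% of the set they were 15.9% of peaks and higher peaks 0.0749%. From 7 gene lists past the threshold, the number went to 13 with nearest genes and 13 within 3 kb, 23 against all genes, 4 with matching on summed peak width, 4 without peaks of the minimum width, 3 against protein-coding genes and 3 there with matching. Of the 7, those settings kept 4, 5, 7, 4, 4, 1 and 1. The rise against all genes follows from a background that includes genes with no peak, which could not be called; the cause of the other shifts was not tested. The 1 list called for higher peaks became 0 with nearest genes (the cause was not tested). Of 20 chromosomes, 18 differed from the rest over all peaks and 9 among peaks at gene ends, which are fewer. The excess of lower peaks on X turned to an odds ratio of 0.87 there (exact adjusted p = 0.348). Depth is unknown, so its limits cannot be given.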

Other observations

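All tests in this part were chosen after the results were seen, except those of olfactory receptor genes against drawn width-matched peaks and over 50 kb from gene ends, and those of X over all peaks and at gene ends, whose technical explanation was named after they were seen.

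Lower peaks clustered. Of 12744 pairs of neighbouring peaks within 5 kb, both were lower in 633. Shuffling the calls within chromosome, gene-end class and width class gave 226 to 335 pairs over 10000 shuffles (mean 278, ratio 2.28, permutation p = 1e-04, the smallest they can give), so these shared properties do not account for all of it. Lying inside a gene, as 70.5% of lower and 49.1% of unchanged peaks did, was not held fixed, and neighbouring peaks may share it. The hypothesis that H2A.Z may fall over stretches longer than 1 peak was found and tested on the same peaks, and shared position inside genes stays open beside it.

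Genes of olfactory and vomeronasal receptors were nearest to 12 of 318 higher peaks (3.77%) and to 416 of 52013 unchanged peaks (0.80%). Against 1 draw of unchanged peaks of the same widths the odds ratio was 3.08 (0.982 to 9.65, 12 against 4 peaks), which leaves open whether narrow peaks in general may lie there. Against all unchanged peaks in width strata, a test added after that draw, it was 3.48 (1.93 to 6.29, permutation p = 3.40e-04), an excess that width does not remove. Over 50 kb from gene ends the odds ratio was 0, with 0 higher peaks near such genes, so that test covers none of the 12 peaks.

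That 96.6% of changed peaks were lower could come from a loss of signal shared by all peaks in the doxycycline libraries, such as weaker libraries or their scaling. The widest decile of peaks had 9.90% lower (9.16 to 10.7%) against 14.8% over all, but width is not height, so a shared loss cannot be told apart from local loss without values per library. The gene-end, gene-list and chromosome differences share this limit. Doxycycline itself and R-loop removal also stay open, as untested.

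ERVK elements among higher peaks had 3 technical explanations. If narrow peaks of either list lay in such repeats, the odds ratio of higher against lower would vanish at the minimum width, but it was 7.10 (4.48 to 11.2). If distance from genes were the cause, it would vanish over 50 kb from a TSS, where it was 14.8 (9.79 to 22.5). Of the peaks there, 687 of 1459 lower and 0 of 209 higher were in L1Md. Each peak carries 1 annotation, so L1Md lowers the ERVK share of lower peaks and raises this ratio. The lists thus differed in ERVK far from genes too. How common ERVK peaks are there is unknown, since unchanged peaks carry no repeat annotation, so distance is not excluded. If reads shared between repeat copies raised all young repeats, L1Md peaks would be mostly higher, but 0.104% of 966 were. Read sharing specific to RLTR13 elements stays open, since mappability was not analysed, and a response of these elements to R-loop removal is untested. Read sharing among L1Md copies stays open too for the lower peaks.

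On X, 20.4% of peaks were lower against 14.6% on autosomes (odds ratio 1.5, 1.32 to 1.70). Fewer copies of X in treated cells would lower the signal of all its peaks, at gene ends too. There, among a part of the same peaks, X showed no excess over autosomes (odds ratio 0.87, 0.682 to 1.11). That gives no sign of fewer copies, but calls are not levels, so a small change of copies is not excluded. L1Md elements may account for the excess, since they hold 112 of the 303 lower peaks of X and 848 of the 8765 of autosomes, and the odds ratio without lower L1Md peaks was 1.05 (0.897 to 1.22). But unchanged L1Md peaks carry no annotation and stayed in, so the ratio would fall wherever X has more L1Md peaks, even if these were lower no more often than other peaks, and the explanation cannot be told apart from others.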
